A study of Mus musculus with 16 samples.

How the data were processed

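Liver RNA from 16 samples of male mice was hybridised to whole-transcript arrays, 4 each from fed wild type, fed vanin-1 knockout, fasted wild type and fasted knockout mice. Per the submitters' processing notes the deposited values are log2 intensities made by RMA, which by default corrects background, quantile normalises and summarises each probe set. The version, the software and the array's library files are not given in the sources used here. The table held 35556 probe sets with values from 1.26 to 14.19 and array medians from 5.19 to 5.29. Labelling used biotin and an Ambion kit for whole transcripts. The labels do not say in words that each array comes from a separate animal, so the p-values measure the spread between these samples.

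From these values the following was computed. A table pairing probe sets with genes named 23099 probe sets, 21218 with 1 gene symbol and 1881 with several, and 12457 were not in it. Only probe sets with 1 symbol were used, 21185 of which matched a RefSeq gene by Entrez ID (assembly GRCm38.p6, used only for names and for which genes neighbour each other), and 0 symbols had to be updated. No coordinates are printed because the array's genome build is not given in the sources used here. Where a gene had more than 1 probe set (1386 genes), the one with the highest mean over the 16 arrays was kept, which left 18820 genes. No filter on dim genes was applied.

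Comparisons used limma 3.58.1 in R 4.3.3, with a mean per group fitted to all 16 arrays (12 residual and 4.66 prior degrees of freedom) and empirical Bayes moderation. The contrasts were fasted knockout against fasted wild type, fed knockout against fed wild type, fasted against fed in each genotype, and the difference of the fasting responses. Tests were two-sided, and p was adjusted by Benjamini-Hochberg over all genes of a contrast and called below 0.05. The 27 gene lists (771 genes, 711 memberships measured and 97 not) covered lipid, glucose and amino acid pathways, stress and immune responses, sex-biased genes, the clock, proliferation, markers of other cell types and tissues, substrain markers and the genes around Vnn1. Vnn1 belongs to no list. Lists were tested by camera with a preset correlation of 0.01, adjusted over the lists of a contrast, beside camera with an estimated correlation and fry. Fry asks whether a list's genes move one way on balance and does not compare them with other genes. The mean of each list per array was also compared by exact permutation, where 4 against 4 arrays cannot give a two-sided p below 0.0286. Under the alternative settings the list test was the preranked form of camera (cameraPR) on z-scores of the moderated statistic.

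The contrasts, lists, thresholds, most alternatives and the rule for named genes were fixed before the data were examined. The rule took Vnn1, the 6 largest rises and the 6 largest falls among called genes whose higher group mean lay above the median of all tested means, up to 3 called members of each list in its main direction and up to 2 in the other, and for a called list without called members the 2 with the smallest p. Predicted genes and olfactory receptors were skipped. The text prints a part of the genes the rule took, chosen after their values were seen and, for the fasting comparisons, after genes whose call hung on single arrays had been left out. Of the called genes that lost their call without a single array, 26 in wild type and 14 in knockout fasting are not named, so the named genes hold their calls more often than the genes the rule took. Cpne5, Ctrb1, Cpa1, Saa2, Lcn2, Arntl, Pde7b and Raet1e fall outside the rule.

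Alternatives were median centring, quantile and cyclic loess normalisation, filters at the 30th and 50th percentile of mean level, the mean of a gene's probe sets, every probe set of the table, a trended or robust variance prior, array weights, only the groups compared, blocks for title number and plate position, a fit without the 3 arrays whose name ends in 2, thresholds of 0.01 and of 1.5-fold, and leaving out each array in turn. The 3 arrays whose name ends in 2 were fasted KO 1, fed WT 2 and fed KO 4, and what the ending stands for is not known here. A fit without fasted WT 4 and fed KO 4, the exact permutation of list means, and contrasts averaged over the other factor were added after the data were examined. The procedure was tested on simulated arrays of 18820 genes with 50 genes changed at each of 4 sizes. At 2-fold it recovered 96.0% for fasted knockout against wild type, 96.0% for fed knockout against wild type, 96.0% for wild type fasting and 98.0% for knockout fasting. At 1.5-fold it recovered 84.0%, 72.0%, 84.0% and 76.0% in the same order. With many changed genes planted, the simulations called 202, 193, 202 and 198 genes in that order. The p needed for a call was therefore less strict than in the real genotype comparisons, which called 3 and 1 genes. The recovered shares do not carry over to those comparisons. A simulated shift of 0.3 in the PPARα list was called in all 4, where the other 26 lists gave 0, 0, 0 and 1 calls. The simulated genes varied independently of each other. These counts therefore do not show how camera performs where the genes of a list vary together. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.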

Results

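Gene expression was measured by whole-transcript array in 16 liver samples from male mice aged 14 to 16 weeks. The samples formed 4 groups of 4 arrays, from wild type (C57Bl/6J) and vanin-1 knockout mice that were either fed or fasted for 24 h. Vanin-1, the product of Vnn1, is a membrane-bound pantetheinase that splits pantetheine into pantothenate and cysteamine. The values were log2 RMA intensities between 1.26 and 14.19, with array medians between 5.19 and 5.29. Arrays of 1 group correlated at 0.986 to 0.993 across genes, and 18820 genes were tested. Levels below are log2 group means ± SD (n = 4 in every group), and arrays are named by group and title number. A fold is given as a lower limit (at least) where the lower of the group means lay under the highest array median, since arrays give little signal over background at such levels. The number of arrays limits the precision of every value.

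The targeted gene was checked first, because it shows whether each array carried the genotype on its label. Vnn1 (probe set 10362138) lay at 8.91 ± 1.61 in fed wild type and at 3.89 ± 0.12 in fed knockout liver (SD, n = 4), at least 32.5-fold lower (log2 difference -5.02, SE 0.54, limma adjusted p = 9.61e-04). In fasted liver it lay at 10.81 ± 0.69 in wild type and at 3.98 ± 0.30 in knockout mice, at least 114-fold lower (log2 difference -6.83, SE 0.54, limma adjusted p = 1.05e-05). The knockout levels lay near the lower quartiles of the arrays (3.72 to 3.79). The fed call ended with only the compared groups (adjusted p = 0.163) and without the 3 arrays whose name ends in 2 (0.0759), 2 of 34 settings (adjusted p 3.51e-07 to 0.163 over the settings). Wild type liver raised Vnn1 3.73-fold on fasting (limma adjusted p = 0.0397). This rise missed the threshold, at adjusted p between 0.0507 and 0.0983, without any 1 of fasted WT 1, 2 and 4, fasted KO 1 and 4, fed WT 2 and 4, and fed KO 1, 2 and 3. Without fed WT 4 the log2 rise was 1.17, against 1.90 with it. In all, 17 of 34 settings lost the call (adjusted p 0.0111 to 0.158 over the settings), including only the compared groups (0.158), a robust prior (0.0851) and array weights (0.0513). Knockout liver gave a Vnn1 difference of 0.09 on fasting (limma adjusted p = 0.949), both levels being near background.

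**Figure D1:**
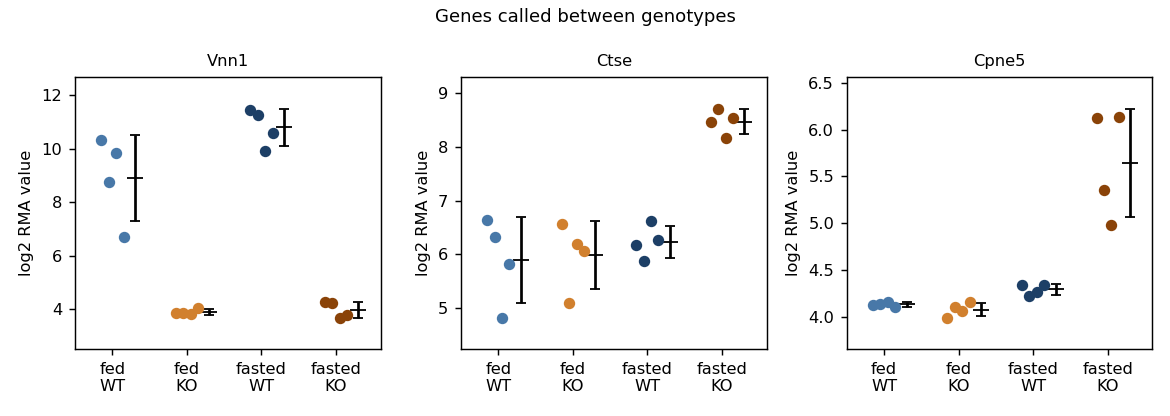
Log2 RMA values of Vnn1, Ctse and Cpne5 on each of the 16 arrays, with the mean and SD of each group of 4. Vnn1 lies at 3.98 ± 0.30 in fasted knockout and 10.81 ± 0.69 in fasted wild type liver, while Ctse and Cpne5 are highest in fasted knockout liver, at 8.47 ± 0.23 and 5.65 ± 0.58.

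The comparison of fasted with fed wild type liver describes the response of the normal liver to 24 h without food. Camera called the lists of PPARα targets (34 of 49 genes higher), ketone body synthesis (5 of 7) and gluconeogenesis and amino acid breakdown (11 of 26) as higher, and those of cholesterol synthesis (18 of 21 genes lower) and fatty acid synthesis (16 of 27) as lower. With an estimated correlation none of these calls held (adjusted p = 0.0619 to 0.0653). Cidec, a lipid droplet protein, rose 6.84-fold, from 5.90 ± 0.74 to 8.68 ± 0.70 (SD, n = 4), and Acot1, a cytosolic acyl-CoA thioesterase, rose 6.92-fold, from 6.50 ± 0.85 to 9.29 ± 0.75. The cell cycle inhibitor gene Cdkn1a rose 10.3-fold, the sodium-calcium exchanger gene Slc8a1 at least 7.12-fold, the fatty acid hydroxylase gene Cyp4a14 6.66-fold and the stress-induced gene Gadd45b 6.58-fold. The largest falls included Hsd3b5, a male-biased steroid dehydrogenase gene, which fell 20.1-fold from 11.17 ± 0.37 to 6.84 ± 0.78. Clec2h fell at least 14.5-fold, Serpina4-ps1 10.2-fold, the cytochrome gene Cyp2c70 6.58-fold, Serpina7, which encodes thyroxine-binding globulin, 7.37-fold, and Thrsp, a regulator of lipogenesis, 6.22-fold. With 1 array left out the log2 difference of Serpina7 lay between -3.64 and -2.35, against -2.88 with all arrays.

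Among the lists that camera called higher in fasted wild type liver, 34 of 49 measured PPARα target genes rose and 15 did not pass the test, with 41 rising when adjusted over the list alone. Their mean log2 difference was 0.98 (camera adjusted p = 5.03e-31, and adjusted p = 0.0653 with an estimated correlation). Of 7 ketone body genes 5 rose, also 5 adjusted over the list alone, among them the fasting hormone Fgf21 (2.78-fold), the monocarboxylate transporter gene Slc16a1 (1.94-fold) and Cpt1a (1.56-fold), which controls fatty acid entry into mitochondria. That list had camera adjusted p = 2.64e-06, and adjusted p = 0.0653 with an estimated correlation. Gluconeogenesis and amino acid breakdown had 11 of 26 genes higher and 15 that did not pass, with 13 higher adjusted over the list alone. Igfbp1, a binding protein of insulin-like growth factors, rose 3.95-fold and Ppargc1a, a coactivator of the gluconeogenic programme, rose 2.78-fold (list adjusted p = 1.30e-09, and adjusted p = 0.0619 with an estimated correlation). In the triglyceride storage and lipoprotein list 12 of 42 genes rose and 1 fell, or 14 and 3 adjusted over the list alone. The droplet coat gene Plin5 rose 3.17-fold and the apolipoprotein gene Apoa4 2.92-fold, while Angptl8, a feeding-induced regulator of lipoprotein lipase, fell 5.30-fold (list adjusted p = 3.63e-05, and adjusted p = 0.0973 with an estimated correlation).

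Cholesterol synthesis fell as a group in fasted wild type liver, with 18 of 21 genes lower, 20 adjusted over the list alone and a mean log2 difference of -1.34 (camera adjusted p = 1.82e-24, and adjusted p = 0.0619 with an estimated correlation). Nsdhl fell 5.07-fold, Sqle 4.41-fold and Fdps 4.32-fold, all enzymes of the sterol pathway. For fatty acid synthesis 16 of 27 genes fell and 1 rose, or 18 and 1 adjusted over the list alone, including the acetoacetyl-CoA synthetase gene Aacs (5.42-fold lower; list adjusted p = 5.52e-13, and adjusted p = 0.0619 with an estimated correlation). Of 22 male-biased genes 7 fell, 8 adjusted over the list alone, such as Keg1 (4.33-fold), and of 19 female-biased genes 7 rose, also 7 adjusted over the list alone. Adjusted p was 1.46e-07 for the male-biased and 1.88e-04 for the female-biased list, and with an estimated correlation the adjusted p was 0.0969 and 0.0619. The female-biased list includes Acot3 (6.37-fold higher), a peroxisomal acyl-CoA thioesterase gene that also stood among the PPARα targets. Vnn3, which encodes another pantetheinase, rose 1.79-fold and Nudt7, a peroxisomal coenzyme A diphosphatase gene, fell 3.47-fold.

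Immune and proliferation lists also lay lower in fasted wild type liver. Of 40 interferon and antigen presentation genes 5 fell, 7 adjusted over the list alone, including Irf1 (1.98-fold) and Psmb10 (1.82-fold), with a list adjusted p of 1.09e-04 and adjusted p = 0.509 with an estimated correlation. The macrophage and Kupffer cell list had 2 of 25 genes lower, 9 adjusted over the list alone (mean -0.27, and -0.18 without fed WT 4; adjusted p = 8.19e-05, and adjusted p = 0.483 with an estimated correlation). The cell cycle list had 2 of 26 genes lower, 4 adjusted over the list alone, among them Ccne1 (at least 1.56-fold; adjusted p = 2.64e-06, and adjusted p = 0.123 with an estimated correlation). On fasted WT 4 the pancreatic enzyme transcript Ctrb1, singled out after its values were seen, lay at 10.1 against a mean of 4.11 on the other 15 arrays. Without that array the interferon list had adjusted p = 0.215 and a mean of -0.094, against -0.26 with it.

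By limma, 1432 of 18820 genes (7.61%) differed between fasted and fed wild type liver, 629 higher and 803 lower, with at least 2-fold changes in 81 and 107 of them. The balance of directions turned with the scaling, to 1014 higher and 542 lower with each array centred on its median and to 708 and 706 with quantile normalisation. At an unadjusted p under 0.05 there were 3997 genes, against 941 by chance. The count was 880 without fasted WT 4 and 990 without fasted WT 4 and fed KO 4. Of the 78 called genes that the rule for named genes took, 50 kept their call whichever single array was left out and 28 lost it, 26 of which are not named for this comparison. The named ones were Vnn1 and Cyp4a14, which was not called without any 1 of fasted WT 3 and 4 and fed WT 2 and 4 (adjusted p up to 0.0636). The log2 rise of Cyp4a14 lay between 1.99 and 3.33 with 1 array left out, against 2.735 with all arrays. Camera called 11 of 27 lists, fry 11, and camera with an estimated correlation 0. The arrays of 10 lists did not overlap between the groups, the smallest two-sided exact permutation p that 4 against 4 arrays allow (0.0286, adjusted 0.0772).

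**Figure D2:**
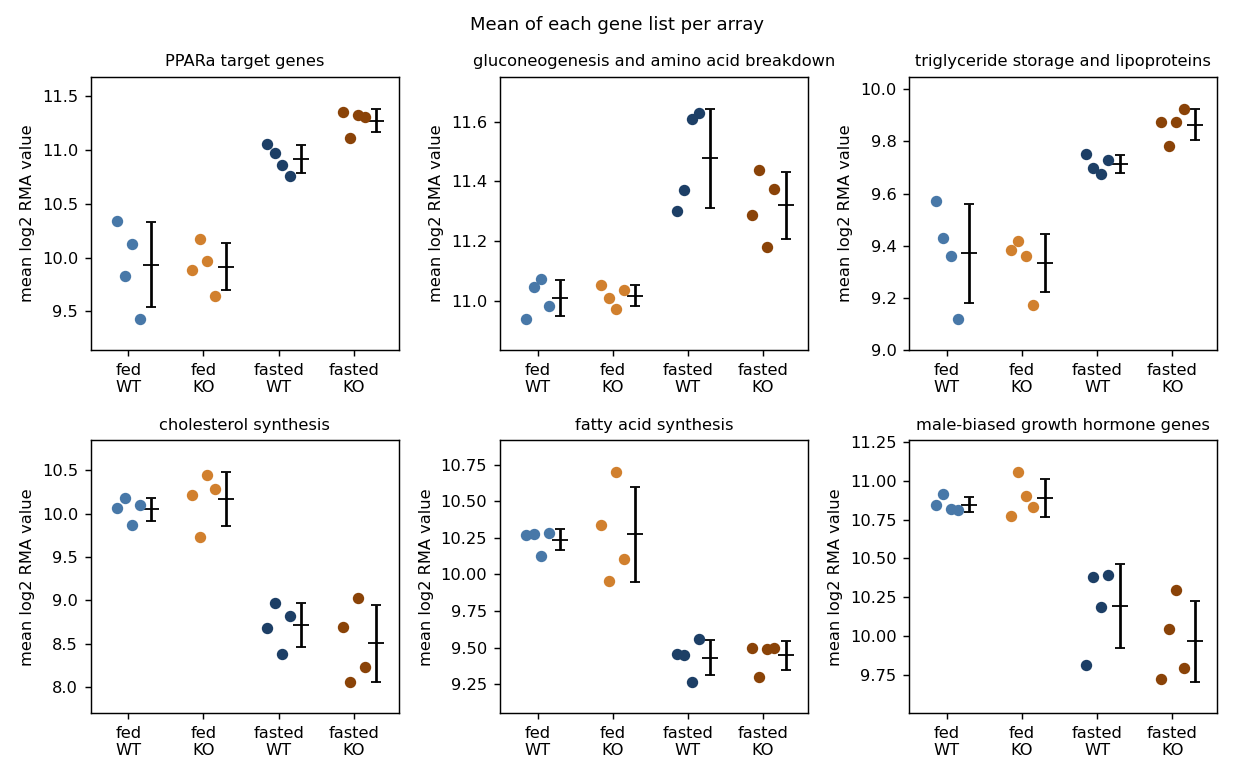
Mean log2 RMA value of 6 gene lists on each of the 16 arrays, with the mean and SD of each group of 4. The PPARα target genes lie at 11.27 ± 0.11 in fasted knockout and 10.91 ± 0.13 in fasted wild type liver.

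The same question was asked of the knockout liver. Cidec rose 19.9-fold on fasting, from 5.46 ± 0.41 to 9.77 ± 0.46 (SD, n = 4), and the acyl-CoA thioesterase genes Acot1, Acot2 and Acot3 rose 18.0-fold, 17.6-fold and 11.6-fold. Gadd45b rose at least 11.0-fold and Cyp4a14 10.9-fold, from 9.79 ± 1.53 to 13.24 ± 0.09. Fed KO 4 lay at 7.53 on Cyp4a14, against 10.16 to 10.74 on the other fed knockout arrays. With 1 array left out the log2 rise of Cyp4a14 lay between 2.69 and 3.765. Hsd3b5 fell 32.7-fold, from 11.18 ± 0.21 to 6.15 ± 0.93, and Thrsp fell by 3.91 on the log2 scale. Lower levels were also found for Cyp2c70 (8.35-fold), Sqle (8.10-fold), Clec2h (at least 7.32-fold) and the organic anion transporter gene Slc22a7 (6.55-fold).

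In knockout liver 40 of 49 PPARα target genes rose on fasting, 44 adjusted over the list alone, with a mean log2 difference of 1.36 (camera adjusted p = 3.04e-40, and adjusted p = 0.0325 with an estimated correlation). Of 7 ketone body genes 5 rose, also 5 adjusted over the list alone, with Fgf21 at least 4.61-fold and Slc16a1 2.58-fold higher (list adjusted p = 1.28e-08, and adjusted p = 0.0325 with an estimated correlation). Triglyceride storage and lipoprotein genes rose in 19 of 42 cases and fell in 3, or 21 and 3 adjusted over the list alone. The glycerol phosphate acyltransferase gene Gpat3 was 3.91-fold higher, Plin5 higher by 1.85 on the log2 scale, and Angptl8 3.75-fold lower (list adjusted p = 1.63e-08, and adjusted p = 0.0325 with an estimated correlation). Gluconeogenesis and amino acid breakdown had 6 of 26 genes higher and 1 lower, or 11 and 1 adjusted over the list alone. Igfbp1 (6.13-fold), the insulin receptor substrate gene Irs2 (2.16-fold) and the glucose-releasing phosphatase gene G6pc (1.48-fold) rose, and the proline dehydrogenase gene Prodh fell 2.11-fold (list adjusted p = 0.00126, and adjusted p = 0.317 with an estimated correlation).

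Cholesterol synthesis fell in 20 of 21 genes of the fasted knockout liver, also 20 adjusted over the list alone, including Msmo1 (6.10-fold) and Idi1 (6.09-fold), with a mean log2 difference of -1.67 (adjusted p = 3.06e-30, and adjusted p = 0.0325 with an estimated correlation). Fatty acid synthesis had 15 of 27 genes lower and 1 higher, the elongase gene Elovl5 (1.61-fold), or 18 and 1 adjusted over the list alone (adjusted p = 3.53e-12, and adjusted p = 0.0428 with an estimated correlation). Male-biased genes fell in 10 of 22 cases, 13 adjusted over the list alone, among them Selenbp2 (6.38-fold), and female-biased genes rose in 7 of 19, 10 adjusted over the list alone, among them the steroid hydroxylase gene Cyp17a1 (4.74-fold). Their adjusted p was 3.21e-11 and 3.17e-05, and with an estimated correlation the adjusted p was 0.0356 and 0.0325. Vnn3 rose 2.31-fold and Nudt7 fell 3.49-fold.

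Further lists were lower in fasted than in fed knockout liver. Cell cycle genes fell in 8 of 26 cases, 11 adjusted over the list alone, such as the topoisomerase gene Top2a (at least 2.12-fold; adjusted p = 5.81e-08, and adjusted p = 0.0768 with an estimated correlation). On the cell cycle list fed KO 4 lay at 5.738, against a mean of 5.315 on fed KO 1 to 3. The camera call held whichever single array was left out, with list means of -0.43 to -0.28. Interferon and antigen presentation genes fell in 5 of 40 cases, or 6 lower and 1 higher adjusted over the list alone, including Irf1 (2.05-fold) and Psmb8 (1.74-fold; adjusted p = 1.32e-04, and adjusted p = 0.486 with an estimated correlation). In the clock list 5 of 20 genes fell, or 7 lower and 3 higher adjusted over the list alone, with the repressor genes Bhlhe40 2.95-fold and Bhlhe41 at least 2.93-fold lower (adjusted p = 0.0306, and adjusted p = 0.356 with an estimated correlation). The acute phase and inflammation list had 6 of 53 genes lower and 2 higher, also 6 and 2 adjusted over the list alone. The chemokine gene Cxcl1 was 4.32-fold, Steap4 3.65-fold and the cytokine signalling inhibitor gene Socs3 2.63-fold lower (adjusted p = 0.00959, and adjusted p = 0.685 with an estimated correlation). Fed KO 4 carried high acute phase transcripts, such as Saa2 at 13.3 and Lcn2 at 12.3, both singled out after their values were seen, and Saa2 lay at 12.06 on fed KO 1. Stellate cell markers fell in 3 of 25 cases, 6 adjusted over the list alone, including the collagen gene Col3a1 (1.62-fold; adjusted p = 0.0165, and adjusted p = 0.486 with an estimated correlation). Macrophage markers fell in 1 of 25 cases, also 1 adjusted over the list alone, the folate receptor gene Folr2 (1.74-fold; adjusted p = 0.0288, and adjusted p = 0.696 with an estimated correlation). Leaving out fed KO 4 ended the acute phase (adjusted p = 0.515), macrophage (0.128), clock (0.0566) and stellate cell (0.0566) calls. The clock call also ended without fasted KO 4 (0.0679) or fed KO 3 (0.0565), the stellate cell call without fed KO 2 (0.0756), and the macrophage call without fasted KO 1 (0.336) or fasted KO 4 (0.126). List means moved by over 1.5 times without fed KO 4 for acute phase genes (-0.34 to -0.10), without fasted KO 1 or 2 for macrophage markers (-0.15 to -0.048 or -0.24), and without fed KO 3 for interferon genes (-0.21 to -0.14).

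By limma, 1772 genes (9.42%) differed between fasted and fed knockout liver, 852 higher and 920 lower, 108 and 138 of them by at least 2-fold, with 4165 at an unadjusted p under 0.05 against 941 by chance. With each array centred on its median the balance turned to 972 higher and 800 lower, and with quantile normalisation to 926 and 901. Of the 78 called genes that the rule took, 64 kept their call whichever single array was left out, and the 14 that lost it are not named for this comparison. Without fasted WT 4 and fed KO 4 the count was 1611. Camera called 14 lists, camera with an estimated correlation 7 and fry 11. For 12 lists the arrays of the groups did not overlap (two-sided exact permutation p = 0.0286, smallest adjusted value 0.0644).

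The fasting responses of the genotypes were then set side by side. Across genes the log2 changes correlated at r = 0.762 (rho = 0.576), where genes are not independent replicates and the contrasts share no array. In both genotypes 861 genes were called, 386 higher and 475 lower and none in opposite directions, against 28.5 and 39.3 expected if the calls were independent. A further 571 genes were called in wild type alone and 911 in knockout alone, and 1411 of the 1432 wild type calls and 1717 of the 1772 knockout calls had the same sign in the other genotype. For the wild type calls the median ratio of the knockout to the wild type change was 0.859. For the knockout calls the median ratio of the wild type to the knockout change was 0.711, each ratio being lowered by selection on its denominator.

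**Figure D3:**
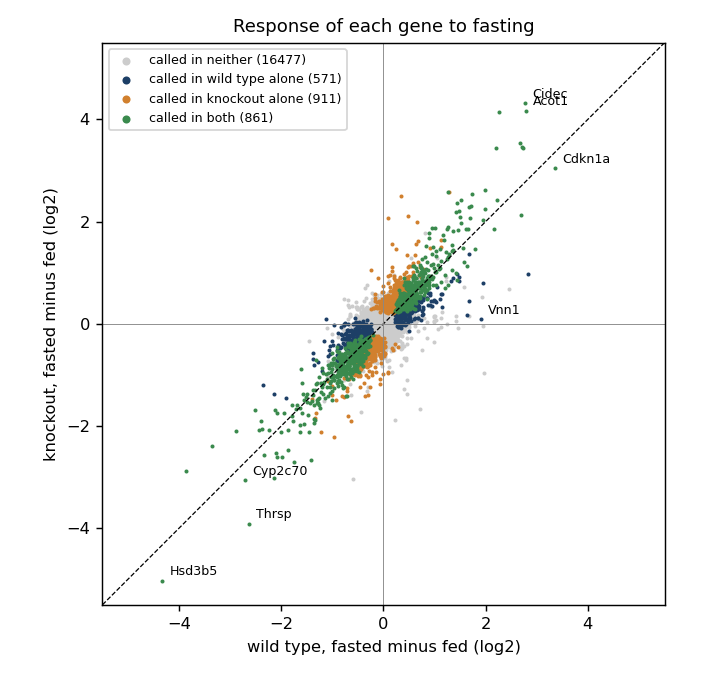
Log2 change on fasting of each of 18820 genes in wild type (horizontal) and knockout liver (vertical), coloured by the genotype in which the gene was called, with the line of equal change dashed. The changes correlate at r = 0.762, and 861 genes were called in both genotypes, all in the same direction.

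The comparison of fasted knockout with fasted wild type liver describes how the genotypes differed in the fasted state. Apart from Vnn1, the genes that differed were Ctse and Cpne5, both higher in the knockout. Ctse (probe set 10349648), which encodes the endolysosomal aspartic protease cathepsin E, lay at 8.47 ± 0.23 in knockout and 6.23 ± 0.30 in wild type liver (SD, n = 4), a 4.73-fold rise (log2 2.24, SE 0.33, limma adjusted p = 0.0224). Cpne5 (probe set 10449551), which encodes copine-5 of a calcium-dependent phospholipid-binding family, lay at 5.65 ± 0.58 against 4.30 ± 0.06, a rise of at least 2.55-fold (log2 1.35, SE 0.18, limma adjusted p = 0.0113). Cpne5 lay below the level the rule for named genes required and was chosen after its values were seen. Ctse was not called, at adjusted p between 0.0538 and 0.157, without any 1 of fasted WT 1, 2 and 4 and fasted KO 1, 2, 3 and 4. It lost its call in 13 of 34 settings (adjusted p 2.96e-04 to 0.248), among them title number as a block (0.0606), a robust prior (0.166), every probe set (0.0684) and the fit without the 3 arrays whose name ends in 2 (0.248). Cpne5 was not called without fasted WT 2 (adjusted p = 0.0748), and neither gene was called without fasted WT 4 and fed KO 4 together (adjusted p = 0.182 and 0.0944). Cpne5 lost its call in 5 of 33 settings (adjusted p 6.55e-05 to 0.378), among them only the compared groups (0.378) and the fit without the 3 arrays whose name ends in 2 (0.188). The SD of Cpne5 was 0.58 in fasted knockout, but 0.058 in fasted wild type, 0.071 in fed knockout and 0.025 in fed wild type liver. In those last groups it lay under the array medians. The SE shared by all groups therefore understates the spread of Cpne5 in fasted knockout liver.

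PPARα target genes lay slightly higher in fasted knockout liver, 48 of 49 with a positive difference and a mean of 0.36 on the log2 scale. Camera called lists in this comparison although limma called 0 of their members at adjusted p under 0.05. The PPARα list mean was 11.27 ± 0.11 in knockout and 10.91 ± 0.13 in wild type liver, and no arrays overlapped (camera adjusted p = 1.83e-15, adjusted p = 0.508 with an estimated correlation, two-sided exact permutation p = 0.0286, adjusted 0.257). Tmem135 showed a log2 difference of 0.34 and the mitochondrial acyl-CoA thioesterase gene Acot2 of 1.59 (limma adjusted p = 0.842 for each). Without fasted WT 1 the Acot2 difference was 2.21 and passed (adjusted p = 0.00922). Triglyceride storage and lipoprotein genes lay higher by 0.15, with no overlap of arrays (adjusted p = 0.00298, and adjusted p = 0.508 with an estimated correlation), with Gpat3 at 7.90 ± 0.10 against 7.37 ± 0.06 and Cidec at 9.77 ± 0.46 against 8.68 ± 0.70. Cidec and Plin5 of that list, like Fgf21 and Cpt1a of the ketone body list, are also PPARα list members, so these calls are not independent. Ketone body genes (0.17) and coenzyme A genes (0.10) lay higher with adjusted p = 0.0279 and 0.0152, and with an estimated correlation the adjusted p was 0.604 and 0.508. Slc16a1 differed by 0.48 and the pantothenate pathway gene Ppcs by 0.46 (limma adjusted p = 0.850 and 0.842). Adjusted over the list alone, 1 ketone body gene was higher and 0 genes of the other lists named here.

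Gluconeogenesis and amino acid breakdown genes lay lower in fasted knockout liver, 22 of 26 with a negative difference and a mean of -0.16. Prodh differed by -0.57 and Cps1, the entry enzyme of the urea cycle, by -0.27 (limma adjusted p = 0.867 for each). The amino acid and ER stress list (mean -0.17, with Sdf2l1 at -0.81) and cholesterol synthesis (mean -0.21, with Insig1 at -0.51) lay lower as well. Camera gave adjusted p = 6.76e-04 for each of these 3 lists, and with an estimated correlation the adjusted p was 0.508, 0.508 and 0.681. Stellate cell markers (mean -0.10, with the collagen gene Col1a2 at -0.41), acute phase genes (mean -0.13, with the cytokine gene Il1b at -0.61) and interferon genes (mean -0.08, with the immunoproteasome gene Psmb8 at -0.40) had adjusted p = 0.00957, 0.0344 and 0.0420, and with an estimated correlation the adjusted p was 0.604, 0.83 and 0.83. The pancreas and adipose list lay lower by -0.70 (adjusted p = 6.91e-06, and adjusted p = 0.508 with an estimated correlation), with Pnliprp1 at 3.47 ± 0.16 against 4.47 ± 1.80. Fasted WT 4 alone carried those digestive enzyme transcripts, with Pnliprp1 at 7.17, and without it the list had a mean of -0.062 and adjusted p = 0.318. By limma 0 members of these lists were called, also 0 adjusted over each list alone.

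The calls of PPARα targets, triglyceride storage, gluconeogenesis and the amino acid and ER stress list held in camera whichever single array was left out, but the mean of the last was -0.099 without fasted WT 4, the array with pancreatic transcripts, against -0.17 with it. Ketone body synthesis ended without fasted WT 4 (adjusted p = 0.533) or fasted KO 1 (0.0591), coenzyme A genes without fasted WT 3 (0.143) or fasted KO 3 (0.0582), cholesterol synthesis without fasted KO 2 (0.163) or fasted KO 4 (0.0713), and stellate cell markers without fasted WT 1 (0.20). Acute phase genes ended without fasted WT 3 (0.623), fasted KO 1 (0.184) or fasted KO 4 (0.279). Interferon genes ended without fasted WT 1 (0.782, with a mean of 0.0093), fasted WT 2 (0.249), fasted WT 3 (0.889), fasted KO 1 (0.116), fasted KO 4 (0.0608) or fed WT 2 (0.0508). List means also moved by over 1.5 times for cholesterol synthesis without fasted WT 2 (-0.13), fasted WT 3 (-0.32), fasted KO 2 (-0.064), fasted KO 3 (-0.39) or fasted KO 4 (-0.12), and for ketone body genes without fasted WT 4 (0.057). They moved as well for acute phase genes without fasted WT 3 (-0.076) or fasted KO 2 (-0.21), and for interferon genes without fasted WT 3 (-0.0065) or fasted WT 4 (-0.25). Camera called 11 of 27 lists, camera with an estimated correlation 0, fry 0 and the exact permutation test 0 after adjustment. Limma called 3 of 18820 genes, with 1033 at an unadjusted p under 0.05 against 941 by chance. That count was 5 without fasted WT 1 or fasted KO 2, 1 without fasted WT 2, and 1 without fasted WT 4 and fed KO 4 together.

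**Figure D4:**
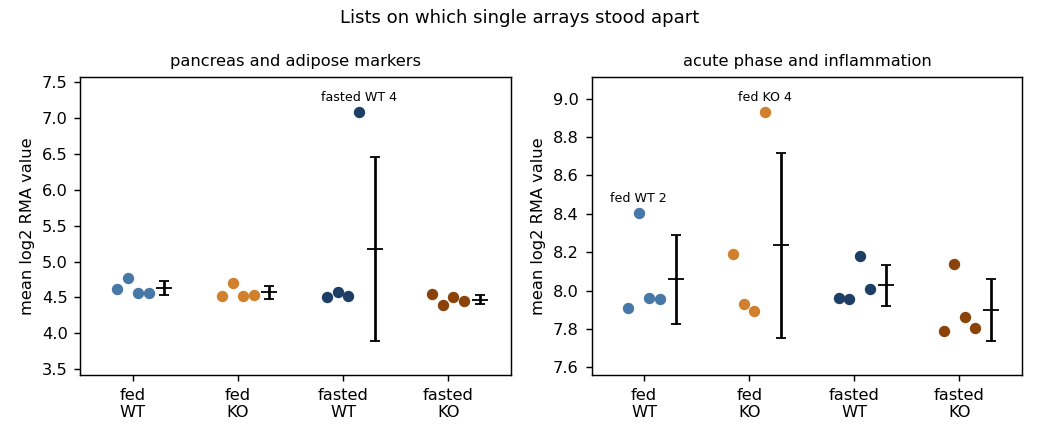
Mean log2 RMA value of the pancreas and adipose list and of the acute phase list on each of the 16 arrays, with the mean and SD of each group of 4. Fasted WT 4 stands at 7.09 on the first list and fed KO 4 at 8.93 on the second.

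In the fed state Vnn1 was the gene that differed between genotypes. Markers of macrophages, lymphocytes and endothelial cells lay lower in fed knockout liver by mean log2 differences of -0.18, -0.16 and -0.09, which camera called. With an estimated correlation none was called (adjusted p = 0.941 for each), and limma called 0 of their genes. The macrophage receptor adaptor gene Tyrobp lay at 8.05 ± 0.14 in knockout and 8.46 ± 0.28 in wild type liver (SD, n = 4), while the macrophage scavenger receptor gene Cd163 was higher in the knockout, at 7.68 ± 0.34 against 6.94 ± 0.45. Among lymphocyte markers Nkg7, of cytotoxic cell granules, lay at 4.86 ± 0.28 against 5.56 ± 0.24 and the chemokine gene Ccl5 at 6.01 ± 0.40 against 6.68 ± 0.26. The endothelial gene Emcn lay at 7.23 ± 0.29 against 7.57 ± 0.33.

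Negative differences were found for 21 of 25 macrophage, 19 of 23 lymphocyte and 20 of 25 endothelial genes, with 0 called by limma adjusted over each list alone. The lists had camera adjusted p = 0.00110, 0.00110 and 0.0426, and fry called none of them. The macrophage call ended without fed WT 4 (0.114) and the endothelial call without fasted WT 3 (0.0628), fed WT 3 (0.0529), fed WT 4 (0.361) or fed KO 4 (0.614), the array with high acute phase transcripts. Without fed WT 4 the macrophage mean was -0.085 and the endothelial mean -0.046, and without fed KO 4 the endothelial mean was -0.038. Camera called 3 lists, fry and camera with an estimated correlation 0. That camera count was 5 without fed WT 1, 6 without fed WT 4 or fed KO 2, and 7 without fed KO 3. Limma called 1 of 18820 genes, with 1084 at an unadjusted p under 0.05 against 941 by chance. The limma count was 2 without fasted WT 3, fasted KO 4, fed WT 3 or fed WT 4, 3 without fed KO 1, and 1 without fasted WT 4 and fed KO 4. Across genes the knockout effects in the fed and the fasted state correlated at r = 0.105 (rho = 0.0414), and Vnn1 was the 1 gene called in both. Without Vnn1 and its chromosome 10 neighbours r was 0.032.

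The interaction contrast asked whether the fasting response differed between the genotypes. The difference of the responses, knockout minus wild type, was 0.81 on the log2 scale for Ehhadh, a peroxisomal beta-oxidation enzyme gene, 0.73 for Fgf21 and 1.54 for Cidec. It was -1.02 for Prodh, -1.25 for Selenbp2 and -0.58 for the mevalonate kinase gene Mvk. None of these passed (limma adjusted p = 0.948 for each). Limma called 0 genes in the interaction, with 924 at an unadjusted p under 0.05 against 941 by chance, and the smallest adjusted p was 0.894. The count was 1 without fasted KO 3.

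At the level of lists camera called 10 in the interaction, and camera with an estimated correlation and fry called 0. The mean difference of the responses, knockout minus wild type, was positive for PPARα targets (46 of 49 genes positive, mean 0.38, adjusted p = 4.64e-07), ketone body genes (0.30, adjusted p = 0.00728), triglyceride storage (0.19, adjusted p = 0.00728) and endothelial markers (0.12, adjusted p = 0.00614). It was negative for gluconeogenesis (-0.16, adjusted p = 0.00171), cholesterol synthesis (-0.33, adjusted p = 4.07e-04), amino acid and ER stress (-0.20, adjusted p = 0.00728), acute phase (-0.31, adjusted p = 0.00728), male-biased genes (-0.27, adjusted p = 0.0299) and the pancreas and adipose list (-0.64, adjusted p = 0.00288). With an estimated correlation the adjusted p was 0.735 for the acute phase list and 0.717 for the others. Members called numbered 0 over all genes, and 1 ketone body gene was higher adjusted over the list alone. Fasted WT 4, with its pancreatic transcripts, and fed KO 4, with its acute phase transcripts, both enter this contrast, and without the pair camera called 6 lists. The calls of PPARα targets, gluconeogenesis and cholesterol synthesis held whichever single array was left out, but their sizes did not all hold. The PPARα mean was 0.24 without fed WT 1, and the cholesterol synthesis mean -0.18 without fasted KO 2 and -0.51 without fasted KO 3.

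The other interaction lists lost their call without single arrays. Without fasted WT 4 the pancreas and adipose list had adjusted p = 0.980, and the ketone body and the amino acid and ER stress lists 0.0666. Without fed WT 1 the ketone body, amino acid and ER stress, and triglyceride lists had adjusted p = 0.0722 and the acute phase list 0.0526. Without fed KO 4 the acute phase list had adjusted p = 0.856, the endothelial list 0.171, the triglyceride list 0.105 and the amino acid and ER stress list 0.0597. The acute phase list also ended without fasted WT 3 (0.194), fasted KO 4 (0.0612) or fed WT 3 (0.0508), and the endothelial list without fed WT 4 (0.0642). The male-biased list ended without fasted WT 2 (0.293), fasted KO 1 (0.258), fasted KO 4 (0.161), fed WT 2 (0.0851), fed WT 4 (0.0619) or fed KO 2 (0.126). Means moved by over 1.5 times without fasted WT 4 for the pancreas and adipose (-0.0049), ketone body (0.18) and amino acid and ER stress lists (-0.13), and without fed WT 1 for the triglyceride list (0.12). They also did without fed KO 4 for the acute phase list (-0.073) and without fed WT 4 (0.072) or fed KO 4 (0.064) for the endothelial list.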

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

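The tests of a whole-array shift, of blood cells, of vanin-1 loss as a source of acute phase transcripts and of the PPARα list, and the counts over splits without Vnn1, were chosen only after the results were seen, unlike the other counts over splits and the held-out pancreas markers. In groups of 4 arrays the highest or lowest value stood apart from the others by Dixon's criterion in 40 of 412 groups tested for the genes and lists in the text, and chance gives about 1 in 20 groups, or 20.6. Genes of the text were chosen after their values were seen, some for an array that stood apart. In a wider set of genes and lists it was 50 of 700 groups, against 35 by chance. The 40 values of the text fell 6 times on fed KO 4, 5 times on fed WT 2, and 4 times each on fasted WT 4, fed KO 3 and fasted KO 2.

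Fasted WT 4 stood apart on the pancreas and adipose list (7.09) and on the digestive enzyme genes Ctrb1 (10.12), Cpa1 (9.89) and Pnliprp1 (7.17). A shift of the whole array is argued against: the list lay 2.56 above fasted WT 1 to 3, while the other 26 lists, whose means the normalisation does not fix, lay between -0.68 and 0.30 from them. Pancreas RNA in the sample may account for it: 13 acinar genes held out of the list lay 2.89 above their mean on the other 15 arrays at the median, 11 of them above every other array and 9 by more than 1 log2 unit. Of the adipose genes of the list, Adipoq (4.65, highest other 4.16), Plin1 (5.62, highest other 5.12), Retn and Aqp7 also lay above every other array. Lep did not, and Car3 lay -1.66 from its mean on the other arrays. On the other 15 arrays 1 of the 17 list genes and 0 of the 13 held-out genes had a mean above 5.77, the median of all tested genes. No biological explanation other than pancreas RNA was tested, and how such RNA would have come into the sample stays open.

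Fed KO 4 stood apart on neutrophil markers (4.76), Steap4 (12.35), Cd163 (8.19), Acot2 (6.98), Clec2h (6.07) and Ehhadh (9.90), and its acute phase list lay 0.93 above the other 3 fed knockout arrays. Blood cells in the sample cannot be judged as a whole. Blood cell markers, measured without globin genes, lay -0.11 from those arrays, and lymphocyte markers, dim at 4.42, lay -0.11 from them. Neutrophil markers, which also come from blood cells, lay 0.68 above. Loss of vanin-1 in the fed liver cannot be told apart as the source: without this array the acute phase list differed by -0.054 (SE 0.15) between fed knockout and fed wild type, against 0.18 with it, a spread too wide to decide. Fed KO 1 also lay high on Saa2 (12.06) and on the list (8.19), where fed KO 2 and 3 lay at 7.93 and 7.89, so an inflammatory reaction in some samples, which the labels do not describe, stays open as a candidate explanation. Fed WT 2 stood apart in the same direction on the acute phase list (8.40), neutrophil markers (4.26), Steap4 (10.97) and Cxcl1 (8.62). Fed KO 4 and fed WT 2 are both among the 3 arrays whose name ends in 2, while fed KO 1 is not. The remaining array of the 3, fasted KO 1, lay lowest of the fasted knockout arrays on the acute phase list (7.79). Whether the ending bears on these values was not tested.

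PPARα target genes responded more to fasting in the knockout by 0.38 in the mean, a difference that camera called and that was lost with an estimated correlation (adjusted p = 0.717), and that was 0.24 without fed WT 1. Pancreas tissue on fasted WT 4 is argued against as the whole cause of the list's difference between the fasted groups (0.36): without that array it was 0.31 (SE 0.080), and the highest of the other wild type arrays (11.06) lay below the lowest knockout array (11.11). A stronger fasting response of all genes cannot be told apart. The list differed by 30.9% of its own fasting change and the other 3396 fasting genes by 6.76% of theirs (exact permutation p = 0.343), and the difference of 24.1 percentage points had a two-sided exact permutation p of 0.0857. Loss of vanin-1 itself therefore stays among the open explanations.

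Camera also called differences between the fasting responses, knockout minus wild type, for ketone body synthesis (0.30), gluconeogenesis and amino acid breakdown (-0.16), cholesterol synthesis (-0.33), triglyceride storage and lipoproteins (0.19), acute phase and inflammation (-0.31), amino acid and ER stress response (-0.20), male-biased growth hormone genes (-0.27), endothelial markers (0.12), and pancreas and adipose markers (-0.64). With an estimated correlation none of the 27 lists passed.

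The knockout effect differed between fasted and fed liver by -1.81 for Vnn1, 2.16 for Ctse and 1.41 for Cpne5, and none was called over all genes (limma adjusted p = 0.948, 0.948 and 0.894). These genes were singled out because they were called in fasted liver, which is part of the same difference, so the sizes are no independent evidence. For Vnn1 both knockout means lay near background (3.98 fasted, 3.89 fed), and the value restates the wild type change on fasting. In fed liver knockout minus wild type was 0.08 for Ctse and -0.06 for Cpne5.

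Among the other arrays, fed WT 2 stood apart on Sqle (9.63), fed WT 1 on Slc16a1 (9.49), fed WT 3 on fatty acid synthesis (10.13) and Insig1 (11.06), and fed WT 4 on Cpt1a (11.41), Psmb10 (9.09) and Slc22a7 (6.59). Fed KO 1 stood apart on Ppargc1a (8.49) and Socs3 (6.51), fed KO 2 on the pancreas and adipose list (4.70) and Apoa4 (11.88), and fed KO 3 on Ppcs (7.25), Ccl5 (6.61), Aacs (10.08) and G6pc (12.12). Fasted WT 1 stood apart on bile duct markers (5.79), and fasted WT 3 on Ccl5 (7.25) and Cpt1a (12.49). Fasted KO 1 stood apart on Col1a2 (5.75) and Cyp4a14 (13.10), fasted KO 3 on bile acid and xenobiotic metabolism (10), and fasted KO 4 on stellate cell markers (7.40). Fasted KO 2 stood apart on fatty acid synthesis (9.30), interferon genes (7.42), lymphocyte markers (4.78) and Saa2 (9.99).

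Other splits of the same 8 arrays into 4 and 4 were used to weigh chance for the counts of called genes. For wild type fasting 1 of 35 splits, the real one, gave as many genes (1432, highest other 1), as it did for knockout fasting (1772, highest other 2). No smaller share is possible with 35 splits. The other splits also mix fed and fasted arrays, which widens the spread within their groups and lowers their counts. Chance is therefore argued against there but not excluded by the splits. For fasted knockout against fasted wild type the real split alone gave 3 (highest other 1), a count that includes the targeted gene. Vnn1 differs in the real split by design, so this count does not exclude chance for the other genes. Without Vnn1 the real split gave 2 and the highest other 1, and the whole count was 1 without fasted WT 2 or without fasted WT 4 and fed KO 4, so the evidence for genes other than Vnn1 stays weak. For fed knockout against fed wild type 5 of 35 splits gave as many (1, highest other 2), so chance is not excluded for a count of that size. The gene counted is Vnn1, and for its own difference chance is argued against: it lay at 4.06 or lower on every fed knockout and at 6.71 or higher on every fed wild type array (log2 -5.02, limma adjusted p = 9.61e-04), and the call held whichever single array was left out. For the interaction the real count was 0, so each of the 100 drawn splits gave as many whatever the data (100 of 100, highest other 1), and the splits decide nothing.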

How the results depend on the processing

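The fit without fasted WT 4 and fed KO 4 and the exact permutation of list means were chosen only after the results were seen. Vnn1 stayed lower in fasted knockout liver and past the threshold under every alternative run and with each array left out (log2 -7.12 to -6.61). In fed liver it stayed lower with each array left out (-5.76 to -4.54), but missed the threshold with only the compared groups (-5.02, adjusted p = 0.163) and without the 3 arrays whose name ends in 2 (-5.14, adjusted p = 0.0759), both with fewer arrays to estimate the spread. Among 214 results of single genes, 258 of the values under alternatives and 249 of those with 1 array left out lost a call. Ctse lost its call in 13 of 34 settings (adjusted p 2.96e-04 to 0.248). Cpne5 lost its call in 5 of 33 (6.55e-05 to 0.378). Cpne5 lay at 4.30 in wild type, under the array medians of 5.19 to 5.29, where arrays give little signal over background.

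Counts of called genes moved by more than 1.5 times as follows, and apart from the settings that use fewer arrays or a stricter threshold the cause was not tested. Fed knockout against fed wild type, 1 gene, gave 2 with median centring, above the 50th percentile, with a trend, with a robust prior, with array weights and with plate row as a random block. It gave 4 with every probe set, and 0 with only the compared groups or without the 3 arrays whose name ends in 2. Fasted knockout against fasted wild type, 3 genes, gave 1 without those 3 arrays, at 0.01, and without fasted WT 4 and fed KO 4. Wild type fasting, 1432 genes, gave 829 with only the compared groups, 576 at 0.01 and 604 at 1.5-fold. Knockout fasting, 1772 genes, gave 964 without the 3 arrays, 879 at 0.01 and 731 at 1.5-fold. Leaving out 1 array gave 1 to 5 and 1 to 3 genes for the fasted and fed genotype comparisons, 880 to 1608 and 1216 to 1861 for wild type and knockout fasting, and 0 to 1 for the interaction.

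The number of called lists was 7 for fasted knockout against wild type at 0.01 and 6 for the interaction without fasted WT 4 and fed KO 4. With an estimated correlation it was 0 for both genotype comparisons, wild type fasting and the interaction, and 7 for knockout fasting. Fry gave 0 for both genotype comparisons and the interaction, and the exact permutation test, which cannot go below p = 0.0286 before adjustment, gave 0 for all 4 group comparisons. Leaving out 1 array gave 8 to 14 and 2 to 7 lists for the fasted and fed genotype comparisons, 10 to 14 and 11 to 15 for wild type and knockout fasting, and 7 to 12 for the interaction. With 1 array left out the correlation of the fasting responses lay between 0.696 and 0.793 and that of the knockout effects between 0.0140 and 0.213. The former was 0.823 for genes above the 50th percentile, and the latter 0.237 without fasted WT 4 and fed KO 4 and 0.032 without Vnn1 and its chromosome 10 neighbours. Results that changed sign were the Vnn1 difference in knockout fasting (-0.0023 to 0.19, negative without fasted KO 1), the interferon list in fasted knockout against wild type (-0.25 to 0.0093, positive without fasted WT 1) and Cpa1 in the same comparison (-1.84 to 0.014, positive without fasted WT 4, alone or with fed KO 4). None of these was past the threshold after the change.

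Title numbers did not pair the arrays: 4 of 24 same-numbered pairs had deviations that correlated above 0.1 (range -0.22 to 0.21), and 3 of 16 arrays matched best with an array of their own number. As a term in the fit the numbers gave 2, 1, 1324, 1658 and 0 genes for fasted and fed knockout against wild type, wild type and knockout fasting, and the interaction. Each plate row held 1 group, so row and group cannot be told apart, and the consensus correlation within rows was -0.0438.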

Other observations

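The averaged contrasts and the tests of the clock genes and of the genes around Vnn1 were chosen only after the results were seen. Averaged over the genotypes, limma called 3440 genes on fasting, 1580 higher and 1860 lower, and averaged over the feeding states it called 1 gene between genotypes, Vnn1. Several lists were not called by camera in either fasting comparison. Phospholipid synthesis had 2 of 25 genes higher in wild type fasting and 3 in knockout fasting, or 3 and 3 adjusted over the list alone (camera adjusted p = 0.275 and 0.0636). Coenzyme A and pantetheine genes had 2 higher and 3 lower of 22 in wild type fasting, or 3 and 4 adjusted over the list alone, with a mean of -0.022, a median of 0.12 and an upward test (adjusted p = 0.751), and 4 higher and 1 lower in knockout fasting, or 5 and 1 adjusted over the list alone (adjusted p = 0.343). Glutathione and oxidative stress genes had 1 higher and 5 lower of 34 in wild type fasting, or 4 and 11 adjusted over the list alone (adjusted p = 0.0537), and 2 higher and 5 lower in knockout fasting, also 2 and 5 adjusted over the list alone (adjusted p = 0.156). Bile acid and xenobiotic genes had 2 higher and 3 lower of 39 in wild type fasting, or 4 and 4 adjusted over the list alone (adjusted p = 0.684), and 2 higher and 6 lower in knockout fasting, or 4 and 8 adjusted over the list alone, with a mean of -0.0041 and a median of 0.028 (adjusted p = 0.425).

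Markers of other cells were not called on fasting in wild type liver, apart from the macrophage list. In wild type fasting camera adjusted p was 0.230 for neutrophil, 0.659 for bile duct, 0.275 for lymphocyte and 0.0694 for endothelial markers. Blood cell markers had 2 of 9 genes lower on fasting in each genotype, also 2 adjusted over the list alone (camera adjusted p = 0.316 in wild type, with a mean of -0.17 against a median of 0.031, and 0.382 in knockout liver). Fry, which does not compare a list with other genes, gave adjusted p = 0.00138 and 0.00796 for that list. The 10 substrain markers were not called between genotypes by camera (adjusted p = 0.649 fasted and 0.941 fed, where mean and median were negative and the test upward). Limma called none of them between genotypes either. Camera asks for a shift of a list in 1 direction, so differences of single markers could escape it. These tests do not show that the genotypes share a substrain. Amino acid and ER stress genes had 6 higher and 2 lower of 28 in wild type fasting, or 6 and 3 adjusted over the list alone (adjusted p = 0.174), and 5 higher and 5 lower in knockout fasting, or 5 and 7 adjusted over the list alone, with a mean of 0.032 and a median of -0.13 (adjusted p = 0.435).

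Clock genes varied between the fed arrays. Arntl, an activator of the clock, lay at 5.83 on fed WT 3 and 5.87 on fed KO 4 but at 7.78 on fed WT 4. A candidate explanation is that the samples were taken at different clock times, which predicts that genes peaking with Arntl and genes peaking at the opposite phase deviate in opposite directions. Deviations from the group means of 5 genes of the Arntl set and 7 genes of the Per2 set correlated at r = -0.837 (two-sided permutation p = 5.3e-04) and rho = -0.847 (p = 5.6e-04) over the 16 arrays, the only pair of sets tried, and at r = -0.864 without the 2 farthest arrays. The test was prompted by opposite values of clock genes on the fed arrays. The correlation partly restates that pattern and is no independent evidence for different clock times. Meal times were not tested and stay open.

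Around Vnn1, 2 of its 100 nearest measured genes had an unadjusted p under 0.01 in the averaged knockout contrast, Pde7b (0.55 higher) and Raet1e (-0.93), with adjusted p = 0.651 for each by limma. DNA of another strain linked to the targeted locus could give such differences, but 31.2% of 16632 windows of the same size elsewhere held as many, so linked DNA and chance cannot be told apart on these few genes. The list of 44 genes around Vnn1 had camera adjusted p = 0.497 fasted and 0.725 fed between genotypes. Its mean differed by -0.07 between fasted knockout and fasted wild type liver with no overlap of arrays (two-sided exact permutation p = 0.0286, adjusted 0.257). The median difference of its genes was smaller, at -0.022, with 27 genes below 0 and 17 above. A single gene with a large difference can carry such a mean, so it does not show a shared shift of the genes around Vnn1. The mean without single genes was not tested.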
